A study of Mus musculus with 96 samples.

How the data were processed

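Liver poly(A) RNA was sequenced in 96 stranded libraries of pregnant C57BL/6J mice, their fetuses and adult male offspring, 3 libraries for each of 32 groups (8 arms at 4 times of day). Mothers were on 12 h light and 12 h dark or on a schedule advanced by 8 h every 5 days, and offspring were on a low-fat or a high-fat diet. The sources used here do not state the day of gestation, the sex or pooling of fetuses, which fetus belonged to which mother, the day of sampling relative to the last advance, or whether the 3 replicates of a group were separate animals, and libraries were treated as independent.

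The deposited values are in FPKM, scaled by the authors to transcript length and to the fragments of the library, in 1 table for each arm with 24883 table entries. The authors named TopHat2 2.1.1, Cufflinks 2.2.1 and the mm10 genome. Their annotation and filters are not given in the sources used here. No counts are held in these tables, so depth and the precision of low values could not be computed, and no scaling common to the 8 tables was visible. Symbols on several table entries (280 symbols, 817 entries) were left out, which left 24066 genes. All 96 columns were used.

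Libraries were scaled by median-of-ratios factors within each stage (mothers, fetuses, offspring), and values were analysed as log2(FPKM + 1). Genes needed an FPKM of at least 1 in at least 3 libraries of the fit. Linear models with moderated variances and an intensity trend were fitted in limma 3.58.1 (R 4.3.3), with 1 mean per arm and time. Level comparisons were differences between arms of the means over the 4 times, with all 48 offspring libraries in 1 fit. Time of day was tested within an arm by an F test with 3 degrees of freedom, and its interaction with the maternal arm by an F test with 3 degrees of freedom. Benjamini-Hochberg adjusted p under 0.05 was the threshold. An arm compared with another holds n = 12 libraries, and libraries in the direction of a change are those of the first arm that lie on its side of the other arm's mean at the same time. Whole lists were tested with camera in limma at a preset correlation of 0.01 between genes, and with the correlation estimated from the data. Of 37 lists of liver pathways and cell type markers, those with at least 3 measured members in a comparison were tested. For their members, p was adjusted over all genes and over the list alone. Peak times and amplitudes came from 24 h cosine fits.

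Genes named in the text followed a rule. For level comparisons it took the 6 largest rises and 6 largest falls among called genes with a mean FPKM of at least 1 in an arm, and the 3 members of smallest p of each list that passed, in its direction. For time of day it took the core clock genes and the called genes with the largest folds, or those of smallest p where none was called, and for interactions the genes of smallest p. Gene models without a name, predicted genes, small RNAs and joined symbols were not eligible for it, and some genes that it selects are not reported here. The rule, the lists, the comparisons and most alternatives were chosen before the data were examined.

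The alternatives were a pseudocount of 0.1, no filter on low values, values as deposited, upper quartile scaling, the replicate number as a block, cosine and sine terms in place of the F test, fits of only the libraries of the 2 arms compared, and leaving out each library in turn. Chosen after the data were seen were the removal of smooth trends with GC content and transcript length from each library, the exclusion of 5 offspring libraries with a median correlation under 0.95 to their arm, the minimum of 3 list members and the summary of peak times. The trends were natural splines with 4 degrees of freedom each, on the longest GENCODE M21 transcript of a symbol, and Python 3.11.15 was used to read the annotation and draw figures. The scaling, the filter and the tests of single genes were run on simulated data with known changes and independent noise for each gene and library. The list tests, the GC and length correction, the peak times and the splits were not simulated.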

Results

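The data were 96 liver poly(A) RNA-seq libraries of C57BL/6J mice in 8 arms of 12 libraries each, with 3 replicates at each of 4 times of day. Zeitgeber time (ZT) counts hours from lights on, and livers were taken at ZT0, ZT6, ZT12 and ZT18. Mothers were kept in 12 h of light and 12 h of dark (control) or had their light schedule advanced by 8 h every 5 days during pregnancy (shifted). Livers of mothers and of fetuses gave an arm for each schedule. Male offspring of both kinds of mother were fed a low-fat or a high-fat diet from 4 weeks of age for 12 weeks, which gave 4 more arms. The tables hold FPKM without counts, so the depth per library is unknown and no counting intervals are given. The sum of FPKM per library ran from 558630 to 628997 in mothers, from 728680 to 1036288 in fetuses and from 546763 to 833499 in offspring. FPKM below were divided by a scaling factor per library. A mean of 12 libraries carries the SD over all 4 times, so it holds the daily rhythm as well as the spread between animals. Folds and log2 changes were fitted on FPKM + 1 and are therefore smaller than the ratio of the mean FPKM of weakly expressed genes. Each arm came in a table of its own, so a difference between tables that is specific to a gene cannot be told from a difference between arms.

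The first question was whether the livers of mothers kept a daily rhythm under the advancing light schedule. In control mothers, Arntl, a transcriptional activator of the core clock, was at 7.17 ± 0.61 FPKM at ZT0 (SD, n = 3), 1.35 ± 0.76 at ZT6, 0.741 ± 0.21 at ZT12 and 7.22 ± 0.85 at ZT18. In shifted mothers it was at 2.26 ± 2.4, 8.29 ± 1.4, 0.324 ± 0.05 and 0.506 ± 0.17 FPKM at the same times (time by arm interaction, adjusted p = 8.47e-05). Dbp, a clock output transcription factor, was at 0.298 ± 0.33 FPKM at ZT0 and 17.3 ± 14 at ZT6 in control mothers, against 10.2 ± 13 and 0.237 ± 0.096 in shifted mothers (adjusted p = 0.00211). Npas2, a partner of Arntl, was at 1.52 ± 0.16 FPKM at ZT0 in control mothers and 0.113 ± 0.17 in shifted mothers, and at 0.0942 ± 0.026 and 1.66 ± 0.49 at ZT6 (adjusted p = 1.66e-06). The period gene Per2 was at 0.784 ± 0.35 FPKM at ZT0 in control mothers and at 9.8 ± 3.9 in shifted mothers (adjusted p = 0.002). Arntl lies on chromosome 7 (113207465 to 113314126, mm10), Dbp on chromosome 7 (45705088 to 45710203), Npas2 on chromosome 1 (39193731 to 39363236) and Per2 on chromosome 1 (91415982 to 91459324).

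Daily profiles of 13 of the 18 measured core clock genes differed between the maternal arms over all genes tested, and of 15 when adjusted over the list alone. Besides Arntl, Dbp, Npas2 and Per2 these included Tef (adjusted p = 8.47e-05), Nfil3 (0.000501), Ciart (0.004), Per3 (0.00786), Hlf (0.0185), Cry1 (0.0193), Nr1d2 (0.0238) and Per1 (0.0445). Peak times from fitted 24 h cosines were later in shifted than in control mothers for 18 of 18 clock genes, by a circular mean of 5.9 h and by 2.6 to 8.2 h, a summary chosen after the profiles were seen. Peaks of genes with little rhythm are poorly placed in it, with an SE of 6.5 h for Cry1 in shifted mothers and of 6.3 and 3.8 h for Rora in control and shifted mothers. In shifted mothers 8 of the 18 genes changed with time. All 8 lost that call with cosine and sine terms (adjusted p from 0.386 to 0.621), so their fitted peaks are weakly determined. Ciart, Dbp, Hlf, Per1 and Per2 had their highest log2 mean at ZT12 in both arms, while that of the other called clock genes moved. Other genes of smallest p were Asap2, Coq10b and Mcm7 (adjusted p = 0.000264 for each). Mcm7, a subunit of the replicative helicase, was at 12.6 ± 1.3 FPKM at ZT18 in control and 2.82 ± 0.026 in shifted mothers (n = 3). The interaction test (limma F test with 3 degrees of freedom) called 175 of 10384 genes. The call of Per1 ended without the filter on low values (adjusted p = 0.0807), with upper quartile scaling (0.0527) and in 18 of 24 fits with 1 library left out, and that of Nr1d2 in 6 of these.

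Time of day changed 439 of 10135 genes in control mothers and 66 of 10003 in shifted mothers. In data simulated with the spread of each arm this test recovered 71.6% of 2-fold and 34.3% of 1.5-fold changes in control mothers, against 37.3% and 5.97% in shifted mothers, so the lower count does not by itself show fewer rhythms. Among the clock genes, 15 of 18 changed in control mothers and 17 when adjusted over the list alone, against 8 and 10 of 18 in shifted mothers. Outside the clock list, Tsku, Eif3j1, Ndrg1, Alas1 and Usp2 had the largest peak-to-trough folds among the genes called in control mothers. There the call of Tsku ended without the filter on low values (adjusted p = 0.0701) and in 8 of 12 fits with 1 library left out, and that of Eif3j1 in 3 of these. Alas1, the first enzyme of heme synthesis, peaked at ZT12 in both arms, 6.48-fold over its trough in control mothers (adjusted p = 0.000823) and 8.69-fold in shifted mothers (0.0128). In shifted mothers Tsku (13-fold), Usp2 (9.15-fold), Loxl4 (5.81-fold) and Coq10b (5.31-fold) completed the 5 largest. Both lists of called genes shared 31 genes, against 2.7 expected if they were independent. The count in shifted mothers rested on few libraries, since it fell to 4, 3 and 2 genes without ZT6 replicate 1, 2 or 3, to 14 without the filter on low values, and to 1 with a cosine test in place of the F test. Without the filter the calls of Arntl, Per1, Per2, Dbp, Tef, Nfil3, Ciart, Tsku, Loxl4 and Coq10b in shifted mothers ended. The count in control mothers ranged from 204 without ZT12 replicate 3 to 697 without ZT6 replicate 3.

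**Figure D1:**
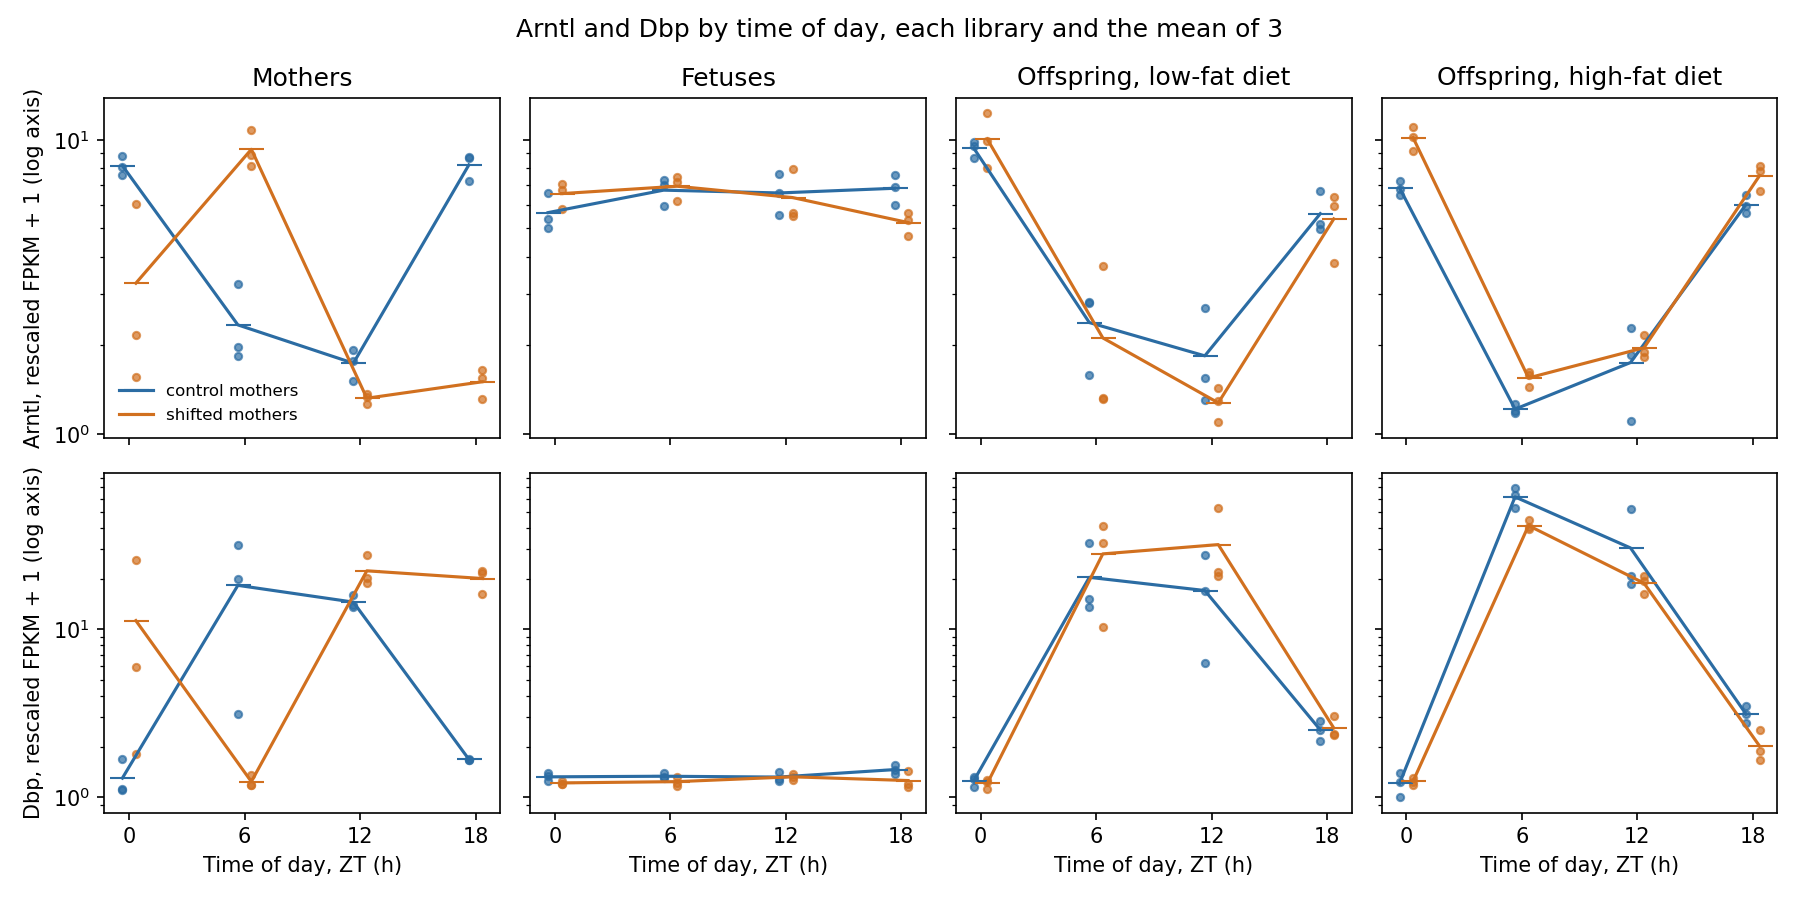
FPKM + 1 on a log axis against ZT (h) for Arntl and Dbp in the 8 arms, with a point per library and a line through the mean of the 3 replicates. In mothers, Arntl was lowest at ZT12 in both arms and highest at ZT6 in the shifted arm only, while the 4 offspring arms had their highest Arntl mean at ZT0.

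The level comparison asked which genes differed between shifted and control mothers over all 4 times. Pnpla3, a lipid droplet lipase that follows feeding, rose from 4.44 ± 5 to 14 ± 12 FPKM (SD, n = 12, log2 change 1.5, SE 0.38, adjusted p = 0.021), and 12 of 12 shifted libraries lay above the control mean of their time. Hamp2, a hepcidin gene, rose from 1530 ± 1000 to 3430 ± 1600 FPKM (log2 change 1.42, SE 0.35, adjusted p = 0.0196, 11 of 12 libraries), and Thrsp, a regulator of lipogenesis, from 338 ± 400 to 566 ± 320 (adjusted p = 0.0467, 11 of 12). Cdkn1a, an inhibitor of the cell cycle, fell from 10.7 ± 8.2 to 3.12 ± 3.4 FPKM (log2 change -1.44, SE 0.26, adjusted p = 0.00383, 10 of 12). Cyp4a14, a fatty acid hydroxylase, fell from 223 ± 140 to 95 ± 57 FPKM (log2 change -1.26, SE 0.34, adjusted p = 0.0282, 11 of 12). The other largest rises were Atp6v0c-ps2 (log2 change 2.56), Sult3a1 (1.31) and Crybb3 (1.24), and the other largest falls were Scand1 (-1.74), Erdr1 (-1.56), Hist1h1c (-1.41) and the transporter gene Abcc3 (-1).

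Endothelial markers fell as a list in shifted mothers (adjusted p = 1.31e-05, median log2 change -0.26, and adjusted p = 0.457 with an estimated correlation). Of the 10 markers, 6 fell over all genes and 8 when adjusted over the list alone, among them Kdr (3.83 ± 0.72 to 2.38 ± 1 FPKM, adjusted p = 0.00546, 11 of 12 libraries), Oit3 (adjusted p = 0.00383) and Clec4g (0.00549). The cell cycle list fell (adjusted p = 0.000991, and adjusted p = 0.629 with an estimated correlation). Of its 15 members, 5 were down over all genes, and 9 down and 1 up when adjusted over the list alone. Its replication factors Mcm5, Mcm6 and Mcm2 fell by log2 changes of -0.78, -0.79 and -0.55 (adjusted p = 0.00136, 0.00346 and 0.0046, in 10, 9 and 9 of 12 libraries). Fat oxidation and ketogenesis fell as a list (adjusted p = 0.000991, and adjusted p = 0.629 with an estimated correlation), although Cyp4a14 was the only 1 of its 24 members called either way. Cpt2 (46.9 ± 4.6 against 41.4 ± 3.7 FPKM, adjusted p = 0.0571) and Ehhadh (132 ± 56 against 89 ± 26, 0.0646) did not pass. Macrophage and Kupffer cell markers fell as a list (adjusted p = 0.00309, and adjusted p = 0.629 with an estimated correlation). Limma called 0 of its 12 members over all genes, and 5 were down when adjusted over the list alone. Csf1r, Adgre1 and Cd68, at log2 changes of -0.39, -0.52 and -0.36, did not pass over all genes (adjusted p = 0.0776, 0.0688 and 0.0624). The unfolded protein response rose as a list (adjusted p = 0.00982, and adjusted p = 0.629 with an estimated correlation). Of its 22 members Xbp1 alone rose, over all genes (68.2 ± 11 to 84.4 ± 12 FPKM, adjusted p = 0.0327) and over the list alone, and Pdia3 and Hsp90b1 were at adjusted p = 0.0553 and 0.0877.

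In all, 871 of 10384 genes differed between the arms of mothers, 359 up and 512 down (limma, median fold 1.24). Of 30 lists tested 5 passed, and the core clock list was the nearest to passing of the rest (adjusted p = 0.133, 3 members up and 1 down, and 5 up and 2 down when adjusted over the list alone). Across genes, which are not independent replicates, the change in mothers had Spearman correlations of -0.22 with GC content and -0.15 with transcript length. The GC and length correction gave 773 genes, 348 up and 425 down. Of the earlier calls with a reference transcript, 58.8% stayed in the same direction, and the 5 lists still passed at the preset correlation. Without the filter on low values the calls of Thrsp, Erdr1 and Abcc3 ended (adjusted p = 0.0768, 0.0798 and 0.0578), and with values as deposited those of Thrsp (0.0508) and Xbp1 (0.14). Of 24 fits with 1 library left out, the calls of Erdr1, Thrsp, Xbp1 and Abcc3 ended in 18, 17, 8 and 6, and without control ZT18 replicate 1 the count was 514.

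In fetal liver the question was whether a daily rhythm was present and whether the schedule of the mother altered it. In control fetuses Arntl was at 4.66 ± 0.81 FPKM at ZT0, 5.74 ± 0.71 at ZT6, 5.6 ± 1 at ZT12 and 5.85 ± 0.78 at ZT18 (n = 3, adjusted p = 0.742). The median fitted clock amplitude was 0.25 on the log2 scale in control fetuses and 0.17 in shifted fetuses, against 1.19 in control mothers. None of the 15 measured clock genes passed over all genes in control fetuses, and Per1, Nr1d2, Tef and Bhlhe40 passed when adjusted over the list alone (adjusted p = 0.0368 for each). In shifted fetuses 0 of 14 passed either way. Egr1 (3.41-fold between ZT18 and ZT6), Plk3 and Cxcl10 had the smallest p in control fetuses, at adjusted p = 0.739, and Dock2, Adgre5 and Npb in shifted fetuses, at 0.824, so that no named gene passed. Limma called 0 of 11754 genes in control and 0 of 11725 in shifted fetuses, with 529 and 615 genes at an unadjusted p under 0.05. The interaction test called 0 of 12009 genes, with 419 at an unadjusted p under 0.05. Etaa1os, Plk3, Egr1, Slc25a10, Sdf2l1 and Xist had its smallest p (adjusted p = 0.911). Adjusted over the list alone, Per1, Per2, Hlf and Bhlhe40 passed the interaction test (adjusted p = 0.0496 for each). The sexes were spread unevenly over the times, since Xist, which is expressed in females, averaged 0.0322 ± 0.021 FPKM at ZT0 and 54.9 ± 8.4 at ZT18 in shifted fetuses. In simulated data of this size the time test recovered 64.2% of genes with a 2-fold change in control and 76.1% in shifted fetuses, so smaller rhythms could pass unseen.

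The level comparison of fetuses asked what the schedule of the mother did to fetal liver over the 4 times. Scand1 fell from 25.9 ± 8.3 to 4.03 ± 2.6 FPKM (SD, n = 12, log2 change -2.51, SE 0.20, adjusted p = 1.22e-06, 12 of 12 libraries). It is a GC-rich gene of 759 nt (68.4% GC) on chromosome 2 (156311847 to 156312704), and it was among the named genes of 4 comparisons. Endog, a mitochondrial nuclease, fell from 10.1 ± 3.1 to 4.33 ± 1.4 FPKM (log2 change -1.06, SE 0.14, adjusted p = 0.000651, 12 of 12). Erdr1 (log2 change -1.20), Zfp771 (-1.15), Hist1h2ag (-1.01) and Tmem238 (-0.99) fell as well. Calcrl, a receptor subunit for calcitonin family peptides, rose from 3.24 ± 0.79 to 5.37 ± 0.9 FPKM (log2 change 0.60, SE 0.10, adjusted p = 0.00258, 12 of 12). Fcho2, Sp3, Zfp800, Cpeb4 and Chac2 rose by log2 changes of 0.70, 0.64, 0.62, 0.58 and 0.58. The 6 largest rises had a GC content between 37.6% and 40.1%, whereas 5 of the 6 largest falls had one between 62.5% and 68.7% and Erdr1 had no reference transcript.

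Oxidative phosphorylation genes fell as a list in shifted fetuses (adjusted p = 2.82e-08, median log2 change -0.18, and adjusted p = 0.684 with an estimated correlation). Of 24 members, 4 fell over all genes and 10 when adjusted over the list alone, including Cox5b (413 ± 65 to 299 ± 66 FPKM, adjusted p = 0.0138), Cox5a (198 ± 44 to 137 ± 31, 0.039) and Atp5b (617 ± 58 to 527 ± 44, 0.0431), each in 12 of 12 libraries. Fat oxidation and ketogenesis fell (adjusted p = 0.00257, and adjusted p = 0.684 with an estimated correlation) with 1 of 23 members called, Cpt2 (19.6 ± 2.8 to 16 ± 2 FPKM, adjusted p = 0.0337, 11 of 12), over all genes and over the list alone. Fatty acid synthesis (adjusted p = 0.00257), hepatocyte maturation (0.0364), periportal hepatocyte markers (0.0366), amino acid catabolism and urea cycle (0.0402) and lymphocyte markers (0.0402) fell with no member called by limma over all genes or over the list alone (adjusted p = 0.684 with an estimated correlation for each list). Srebf1 (log2 change -0.27, adjusted p = 0.066), Me1 (-0.36, 0.113), Scd1 (-0.49, 0.135), Cebpa (-0.43, 0.277) and Cyp2f2 (-0.95, 0.311) were among those that did not pass. Extracellular matrix genes fell as a list (adjusted p = 0.00462, and adjusted p = 0.684 with an estimated correlation) with 0 of 16 members called over all genes and 1 when adjusted over the list alone, and Bgn was at adjusted p = 0.056. Macrophage and Kupffer cell markers fell (adjusted p = 0.0402, and adjusted p = 0.684 with an estimated correlation) with no member called either way, and C1qa, C1qb and C1qc were at log2 changes of -0.34, -0.30 and -0.34 (adjusted p = 0.2, 0.149 and 0.113). Cell cycle genes and erythroid markers rose as lists (adjusted p = 0.0364 for both, and adjusted p = 0.684 with an estimated correlation) with no member called either way, and Mki67 (96.4 ± 29 against 121 ± 36 FPKM, adjusted p = 0.28) and Tfrc (175 ± 73 against 240 ± 100, 0.239) were among them. Of the 34 lists tested these 11 passed, and bile acid synthesis and transport was the nearest to passing of the rest (adjusted p = 0.0533).

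In total 440 of 12009 genes differed between the fetal arms, 243 up and 197 down (limma, median fold 1.26). Across genes, the change had Spearman correlations of -0.37 with GC content and 0.33 with transcript length. After removal of each library's GC and length trends 178 genes were called, 31.3% of the earlier calls stayed, and Atp5b, Cpeb4 and the macrophage list no longer passed (adjusted p = 0.137, 0.0642 and 0.0621). Without the filter on low values the calls of Cox5a (adjusted p = 0.0652), Atp5b (0.0569), Cpt2 (0.0518) and Cpeb4 (0.0688) ended, and with values as deposited those of Atp5b (0.0606) and Cpeb4 (0.0762). With 1 library left out, Atp5b and Cpeb4 were not called in 16, Cox5a in 15 and Cpt2 in 12 of 24 fits. Values as deposited gave 190 genes, and the count ran from 213 without control ZT6 replicate 2 to 870 without shifted ZT0 replicate 3.

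In adult male offspring the time-of-day tests asked whether the schedule of the mother left a mark on the liver clock. Core clock genes cycled in all 4 arms. Arntl peaked at ZT0 in each, at 8.37 ± 0.6 FPKM in low-fat control, 9.06 ± 2.2 in low-fat shifted, 5.86 ± 0.38 in high-fat control and 9.18 ± 0.94 in high-fat shifted offspring (n = 3). Of 18 clock genes, 14, 13, 10 and 17 changed with time in these arms, and 17, 14, 16 and 17 when adjusted over the list alone. Peak times of the clock genes differed between the maternal arms by a circular mean of 0 h on the low-fat and 0.2 h on the high-fat diet. Of the 1444 other genes called in low-fat control offspring, 956 (66.2%) peaked later in low-fat shifted offspring, by a circular mean of 1 h over the 1444, against 30 of 63 (47.6%) and 0 h on the high-fat diet. Among other genes, the lipogenic Thrsp rose 32.9-fold from ZT0 to ZT12 in low-fat control offspring, ahead of Lpin1 (17.6-fold), Rgs16 (17.5-fold), Tsku and Serpina4-ps1. In low-fat shifted offspring Cyp4a14 (36.7-fold), the fatty acid elongase gene Elovl3 (23.3-fold), Serpina4-ps1, Upp2 and Cyp2a5 had the largest folds. Cyp4a14 was at 219 ± 190 FPKM at its peak at ZT6 and did not pass with cosine and sine terms (adjusted p = 0.207), and in low-fat control offspring Serpina4-ps1 did not pass without the filter (0.059). In high-fat offspring Rgs16, Elovl3, Usp2, Thrsp and Upp2 were the 5 largest in both maternal arms, with Rgs16 at 21.3-fold in control and 12-fold in shifted offspring.

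Time of day changed 1458 of 10115 genes in low-fat control, 2530 of 10312 in low-fat shifted, 73 of 9899 in high-fat control and 3018 of 10193 in high-fat shifted offspring. High-fat control offspring held the libraries of lowest median correlation with the rest of their arm, ZT0 replicate 1 (0.879, with 16218 table entries at 0) and ZT12 replicate 2 (0.921), and without them 377 genes were called. The 4 counts are not shown to differ by these tests, which recovered 55.2%, 32.8%, 14.9% and 80.6% of simulated 2-fold changes in the 4 arms in that order. The interaction of time and maternal arm called 12 of 10883 genes on the low-fat diet, with Cyp2c44 and Ubxn1 (adjusted p = 0.0133 for both), Osbp and Gpam (0.0144 for both), Atp2a2 (0.0195) and Mmp15 (0.0295) at the smallest p. Gpam, the first enzyme of glycerolipid synthesis, was at 47.8 ± 27 FPKM at ZT0 and 7.45 ± 3.9 at ZT18 in shifted offspring, against 11 ± 2.8 and 25.8 ± 16 in control offspring (n = 3). That count is fragile, since it was 0 without low-fat control ZT18 replicate 3, 419 without low-fat control ZT18 replicate 1 and 2 with values as deposited. The calls of Ubxn1, Osbp, Atp2a2 and Mmp15 ended with values as deposited and with only the libraries of the 2 arms, that of Cyp2c44 with the former (adjusted p = 0.0709) and that of Gpam with the latter (0.202). On the high-fat diet limma called 0 of 10883 genes for the interaction, with 872 at an unadjusted p under 0.05. Rdh10, Mreg, Golph3, Ubqln2, Zbtb14 and Icam2 had the smallest p there (adjusted p = 0.534 for each). No clock gene passed either interaction test over all genes, and Nr1d2 alone passed when adjusted over the list alone, on the low-fat diet (adjusted p = 0.03).

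On the low-fat diet the level comparison asked what the schedule of the mother left in adult offspring without a dietary challenge. Reln, a secreted matrix protein and stellate cell marker, rose from 2 ± 0.56 to 3.18 ± 0.53 FPKM in offspring of shifted mothers (SD, n = 12, log2 change 0.49, SE 0.07, adjusted p = 0.000157, 12 of 12 libraries). It lies on chromosome 5 (21884454 to 22344702) and was the only 1 of 10883 genes called, with 811 at an unadjusted p under 0.05. Fat oxidation and ketogenesis fell as a list (adjusted p = 2.74e-08, median log2 change -0.34, and adjusted p = 0.432 with an estimated correlation). None of its 24 members passed limma over all genes, and 5 fell when adjusted over the list alone. Slc25a20, the mitochondrial acylcarnitine carrier, was at 69.1 ± 14 FPKM in control and 51.3 ± 10 in shifted offspring (adjusted p = 0.309), Ehhadh at 182 ± 170 and 71.2 ± 31 (0.384) and Acadl at 104 ± 18 and 89.5 ± 20 (0.384).

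Heat shock genes rose as a list (adjusted p = 0.000128, and adjusted p = 0.432 with an estimated correlation), with 4 of 12 members up when adjusted over the list alone and 0 over all genes, where Hsph1, Hsp90ab1 and Hspa1b were at adjusted p = 0.379, 0.384 and 0.498. Stellate cell markers rose (adjusted p = 0.000968, and adjusted p = 0.432 with an estimated correlation) with Reln the only 1 of 8 called over all genes or over the list alone, and Rgs5 and Dcn were at adjusted p = 0.739 and 0.769. Extracellular matrix rose as a list (adjusted p = 0.00118, and adjusted p = 0.559 with an estimated correlation), with 1 of 13 members up when adjusted over the list alone, 0 over all genes, and Bgn at 27.4 ± 9.2 against 35.8 ± 8.9 FPKM (adjusted p = 0.359). Fatty acid synthesis (adjusted p = 0.000367), endothelial markers (0.012) and gluconeogenesis and fasting response (0.0263) rose as lists, and immediate early genes (0.0263) and lipid droplet and lipid storage (0.0408) fell, with no member called by limma over all genes or over the list alone (adjusted p = 0.559 with an estimated correlation for each list). Acaca, Pecam1, Irs2, Jun and G0s2 were at log2 changes of 0.47, 0.22, 0.33, -0.40 and -0.85 (adjusted p = 0.405, 0.497, 0.518, 0.769 and 0.579). Macrophage and Kupffer cell markers rose (adjusted p = 0.0344, and adjusted p = 0.666 with an estimated correlation), with no member called either way and Adgre1 at adjusted p = 0.606. Of the 32 lists tested these 10 passed, and the smallest adjusted p of the rest was 0.159. Without the libraries of median correlation under 0.95, the lists for fatty acid synthesis, gluconeogenesis, endothelial and macrophage markers no longer passed (adjusted p = 0.0637, 0.0742, 0.402 and 0.441), and without shifted ZT0 replicate 2 the gene count was 28. After the GC and length correction the lipid droplet, gluconeogenesis, immediate early and endothelial lists did not pass (adjusted p = 0.0829, 0.0539, 0.06 and 0.065).

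On the high-fat diet the same comparison gave many more calls. Gpam rose from 5.65 ± 3.4 FPKM in offspring of control mothers to 36.6 ± 13 in offspring of shifted mothers (SD, n = 12, log2 change 2.52, SE 0.23, adjusted p = 2.11e-09, 12 of 12 libraries; chromosome 19, 55067268 to 55127238). Scd3, a stearoyl-CoA desaturase, rose from 0.462 ± 0.56 to 7.45 ± 4.8 FPKM (log2 change 2.29, SE 0.33, adjusted p = 1.08e-06, 12 of 12). Mia2, which acts in export of large cargo from the endoplasmic reticulum, rose from 2.62 ± 1.8 to 23.8 ± 7.3 FPKM (log2 change 2.85, SE 0.30, adjusted p = 9.02e-09, 12 of 12). Igfbp2, a binding protein of insulin-like growth factors, fell from 311 ± 98 to 141 ± 60 FPKM (log2 change -1.21, SE 0.18, adjusted p = 2.39e-06, 12 of 12). Tgoln2 (log2 change 3.10), Rnf125 (2.26) and Apoo-ps (2.22) were the other largest rises, and Tff3 (-2.21), Serpina4-ps1 (-1.65), Eif4ebp3 (-1.40), the glutathione transferase gene Gstp2 (-1.37) and Selenbp2 (-1.30) the other largest falls.

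Fatty acid synthesis rose as a list (adjusted p = 0.033, median log2 change 0.72, and adjusted p = 0.973 with an estimated correlation). In it, 12 of 17 members were up and 1 down over all genes and over the list alone. Fads2, a fatty acid desaturase, rose from 164 ± 72 to 444 ± 150 FPKM (log2 change 1.48, SE 0.17, adjusted p = 3.88e-08, 12 of 12 libraries), and Acaca, which makes malonyl-CoA, from 7 ± 4.4 to 11.5 ± 3.5 (log2 change 0.74, adjusted p = 0.000333, 12 of 12). Fat oxidation and ketogenesis rose as well (adjusted p = 0.033, median 0.52, and adjusted p = 0.973 with an estimated correlation). Here 11 of 24 members were up over all genes and over the list alone. Acadm, the medium-chain acyl-CoA dehydrogenase gene, rose from 104 ± 19 to 152 ± 27 FPKM (adjusted p = 4.7e-06), Cpt1a, which controls entry of fatty acids into mitochondria, from 56 ± 14 to 90.9 ± 22 (6.7e-05) and Hadhb from 74.4 ± 21 to 112 ± 12 (9.16e-05), each in 12 of 12 libraries. Oxidative phosphorylation fell as a list (adjusted p = 0.00169, median log2 change -0.36, and adjusted p = 0.973 with an estimated correlation). Its members were down in 15 and up in 3 of 24 cases over all genes and over the list alone. Cox6c fell from 946 ± 210 to 540 ± 95 FPKM, Ndufa5 from 239 ± 120 to 115 ± 28 and Atp5o from 284 ± 47 to 181 ± 33 (adjusted p = 1.98e-07, 2.9e-07 and 1.15e-07, each in 12 of 12 libraries). Of 32 lists these 3 passed, and gluconeogenesis and fasting response was the nearest to passing of the rest (adjusted p = 0.242, 6 of 12 members up over all genes and over the list alone).

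Of 10883 genes, 5235 differed between the maternal arms on the high-fat diet, 3083 up and 2152 down (limma, median fold 1.33). Across genes, the change had Spearman correlations of -0.31 with GC content and 0.44 with transcript length, and the GC and length correction gave 4512 genes, 2143 up and 2369 down, and ended the call of the oxidative phosphorylation list (adjusted p = 0.328). Both lipid lists lost their calls with values as deposited (adjusted p = 0.229 for synthesis and 0.14 for oxidation) and without the libraries of median correlation under 0.95, 2 of which were high-fat control libraries (0.131 for both).

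**Figure D2:**
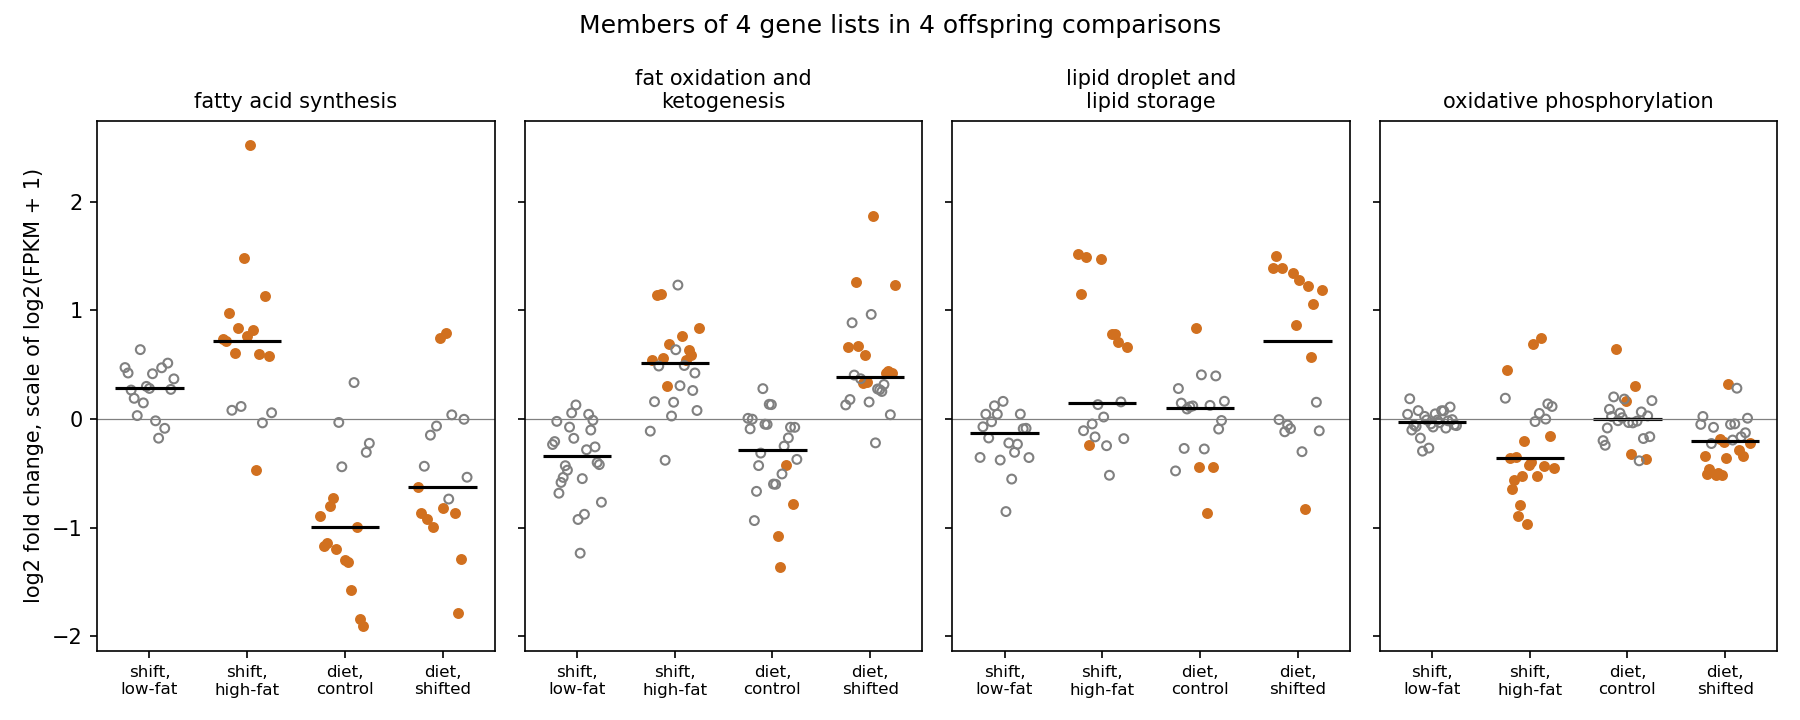
Log2 fold change of each member of lists tested in offspring, by comparison, with filled orange points for adjusted p under 0.05, open grey points for the rest and a black line at the median. Fat oxidation and ketogenesis had a median of -0.34 for shifted against control offspring on the low-fat diet and 0.52 on the high-fat diet.

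The diet comparison in offspring of control mothers gives the effect of high-fat feeding without a maternal shift. Scd1, the main liver stearoyl-CoA desaturase, fell from 2230 ± 970 FPKM on the low-fat to 645 ± 530 on the high-fat diet (SD, n = 12, log2 change -1.91, SE 0.35, adjusted p = 0.000463, 12 of 12 libraries). Fasn, the fatty acid synthase, fell from 109 ± 83 to 38.4 ± 26 FPKM (log2 change -1.30, SE 0.23, adjusted p = 0.000366, 10 of 12). Gpam fell from 16.3 ± 11 to 5.65 ± 3.4 FPKM (log2 change -1.32, adjusted p = 0.00039, 11 of 12) and malic enzyme Me1 from 125 ± 70 to 38.2 ± 17 (-1.57, 0.000399, 12 of 12). Fatty acid synthesis fell as a list (adjusted p = 4.99e-09, median log2 change -0.99, and adjusted p = 0.508 with an estimated correlation), with 12 of 17 members down over all genes and 13 when adjusted over the list alone. Pericentral hepatocyte markers rose as a list (adjusted p = 0.00694, and adjusted p = 0.968 with an estimated correlation), with 5 of 10 members up over all genes and over the list alone. Cyp1a2 rose from 167 ± 67 to 241 ± 49 FPKM (adjusted p = 0.0148, 12 of 12), Slc1a2 from 17.4 ± 6.5 to 26.1 ± 4.7 (0.0172, 12 of 12) and Lgr5 from 0.686 ± 0.34 to 1.22 ± 0.77 (0.0149, 10 of 12). Scand1, Enho, H2afj, Tmem238, Sult5a1 and Erdr1 were the largest rises (log2 changes 2.75, 1.53, 1.53, 1.5, 1.48 and 1.42). Fabp5 (-2.99), Pnpla3 (-1.84), Rgs16 (-1.68) and Ugt1a9 (-1.54) completed the largest falls.

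In these offspring 1587 of 10883 genes differed between diets, 717 up and 870 down (795 and 693 with the GC and length correction), and the endothelial list was the nearest to passing of the other lists among the 32 tested (adjusted p = 0.0633). Across genes, the change had Spearman correlations of 0.35 with GC content and -0.16 with transcript length. A fit of the 24 libraries of these 2 arms alone called 884 genes and ended the calls of Erdr1 and Slc1a2 (adjusted p = 0.0642 and 0.0594), while the count was 1056 without low-fat control ZT6 replicate 2, 2495 without high-fat control ZT0 replicate 2 and 2599 without high-fat control ZT12 replicate 1.

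The diet comparison was also run in offspring of shifted mothers. Acadm rose from 97.9 ± 30 to 152 ± 27 FPKM (SD, n = 12, log2 change 0.66, SE 0.09, adjusted p = 1.29e-06, 11 of 12 libraries) and Vnn1 from 12.3 ± 10 to 28.9 ± 13 (1.23, adjusted p = 0.00125, 9 of 12). The fat oxidation and ketogenesis list rose (adjusted p = 9.08e-06, and adjusted p = 0.779 with an estimated correlation). Its members rose in 11 of 24 cases over all genes and 13 when adjusted over the list alone. Lipid droplet and lipid storage rose (adjusted p = 0.00979, and adjusted p = 0.779 with an estimated correlation). Of these genes 10 of 18 were up and 1 down over all genes, and 10 up and 2 down when adjusted over the list alone. Pparg, a regulator of lipid storage, rose from 2.43 ± 1.8 to 6.8 ± 3.7 FPKM (adjusted p = 7.19e-05, 10 of 12), Fitm2 from 6.69 ± 3.3 to 12.6 ± 4.5 (5.06e-05, 10 of 12) and Mogat1 from 0.324 ± 0.21 to 2.48 ± 1.9 (3.27e-05, 11 of 12). Fatty acid synthesis fell (adjusted p = 0.0034, and adjusted p = 0.779 with an estimated correlation). Among its members 8 of 17 were down and 2 up over all genes, and 9 down and 2 up when adjusted over the list alone. Elovl6 fell from 55.6 ± 36 to 24.2 ± 13 FPKM (adjusted p = 0.00182, 12 of 12), Acss2 from 99.7 ± 38 to 53.2 ± 25 (0.00128, 11 of 12) and Pnpla3 from 5.9 ± 6.8 to 0.404 ± 0.37 (0.000202, 11 of 12).

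Oxidative phosphorylation fell as a list with the high-fat diet in these offspring (adjusted p = 9.08e-06, and adjusted p = 0.779 with an estimated correlation). There, 12 of 24 members were down and 1 up over all genes, and 13 down and 1 up when adjusted over the list alone. Atp5o, Cox4i1 and Ndufb8 fell by log2 changes of -0.50, -0.47 and -0.36 (adjusted p = 2.92e-05, 4.34e-05 and 0.000268, in 9, 11 and 9 of 12 libraries). Extracellular matrix fell (adjusted p = 0.00481, and adjusted p = 0.779 with an estimated correlation), with 7 of 13 members down over all genes and over the list alone, such as Lum (4.31 ± 1.8 to 2.44 ± 0.59 FPKM, adjusted p = 0.0146), Mmp2 (0.019) and Bgn (0.0196). The largest rises were Cfd (log2 change 3.10), Cyp4a14 (1.86), Cyp2b9 (1.83), Mia2 (1.67), Apoo-ps (1.62) and Scand1 (1.56). The largest falls were Fabp5 (-4.72), Tff3 (-2.47), Pdzk1ip1 (-2.42), Atp6v0c-ps2 (-2.36), Chrna4 (-1.84) and Pnpla3 (-1.79).

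In offspring of shifted mothers 2591 of 10883 genes differed between diets, 1449 up and 1142 down, and the smallest adjusted p of the lists that did not pass, of 32, was 0.131 for lipid-associated macrophage markers. Both diet comparisons shared 408 called genes, against 377.8 expected if independent, and 226 of them moved the same way, against 186.8 expected, while the changes of all genes had a Spearman correlation of -0.07 across genes. After the GC and length correction 255 of 350 shared genes moved the same way, against 142.7 expected (Spearman 0.04). Across genes, the change had Spearman correlations of -0.23 with GC content and 0.42 with transcript length, and the GC and length correction gave 2014 genes and ended the oxidative phosphorylation call (adjusted p = 0.0545). The call of Cyp4a14 ended without the filter on low values (adjusted p = 0.0519), those of Atp6v0c-ps2 and Lum with a pseudocount of 0.1 (0.0513 and 0.0949) and that of Bgn with values as deposited (0.1).

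The maternal shift by diet interaction asked whether the response to high-fat feeding differed between offspring of shifted and of control mothers. Fat oxidation and ketogenesis had a more positive diet response after a maternal shift (adjusted p = 5.38e-06, median log2 difference 0.75, and adjusted p = 0.983 with an estimated correlation). Of 24 members, 15 were higher over all genes and 17 when adjusted over the list alone. Ehhadh, a peroxisomal enzyme, went from 182 ± 170 FPKM on the low-fat to 49.7 ± 14 on the high-fat diet in offspring of control mothers, and from 71.2 ± 31 to 82.6 ± 18 in offspring of shifted mothers (SD, n = 12, log2 difference 1.64, SE 0.38, adjusted p = 0.00242). Acadm differed by 0.75 (SE 0.12, adjusted p = 0.000215), and Gpam, at 16.3 ± 11 and 5.65 ± 3.4 against 27.1 ± 22 and 36.6 ± 13 FPKM, by 2.11 (SE 0.33, adjusted p = 0.000165).

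Oxidative phosphorylation had a more negative diet response after a maternal shift (adjusted p = 0.000985, median log2 difference -0.29, adjusted p = 0.983 with an estimated correlation and 0.246 after the GC and length correction). Members were lower in 12 and higher in 2 of 24 cases over all genes, and 14 lower and 2 higher when adjusted over the list alone. Atp5o, Ndufa9 and Cox4i1 differed by -0.59, -0.38 and -0.49 (adjusted p = 0.000748, 0.00137 and 0.00201). Endothelial markers had a more negative response (adjusted p = 0.0212, and adjusted p = 0.983 with an estimated correlation), with 5 of 10 lower over all genes and over the list alone, among them Clec4g (-0.69, adjusted p = 0.00201), Fcgr2b (-0.49, 0.0108) and Stab1 (-0.54, 0.0263). Of the lists that did not pass, of 32, the smallest adjusted p was 0.185 for lipid droplet and lipid storage. The largest positive differences were Mia2 (2.55), Cyp4a14 (2.47), Apoo-ps (2.38), Gpam, Sntb1 (2.04) and Acss3 (2.02). The largest negative ones were Tff3 (-2.01), Serpina4-ps1 (-1.80), Selenbp2 (-1.59), Igfbp6 (-1.51), Gstp2 (-1.40) and Eif4ebp3 (-1.36).

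The interaction called 2669 of 10883 genes, 1646 positive and 1023 negative (limma). Across genes, the difference had Spearman correlations of -0.39 with GC content and 0.40 with transcript length. The GC and length correction gave 1715 genes, 830 positive and 885 negative, and ended the calls of the oxidative phosphorylation list (adjusted p = 0.246), Cox4i1 (0.132), Cyp4a14 (0.0617), Tff3 (0.0587) and Serpina4-ps1 (0.0843). With 1 of the 48 libraries left out, the call of Serpina4-ps1 ended in 29 fits and that of Cyp4a14 in 17. Without the libraries of median correlation under 0.95 the endothelial list did not pass (adjusted p = 0.211), and with values as deposited the calls of Ndufa9, Fcgr2b and Stab1 ended (0.0989, 0.0946 and 0.0775).

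**Figure D3:**
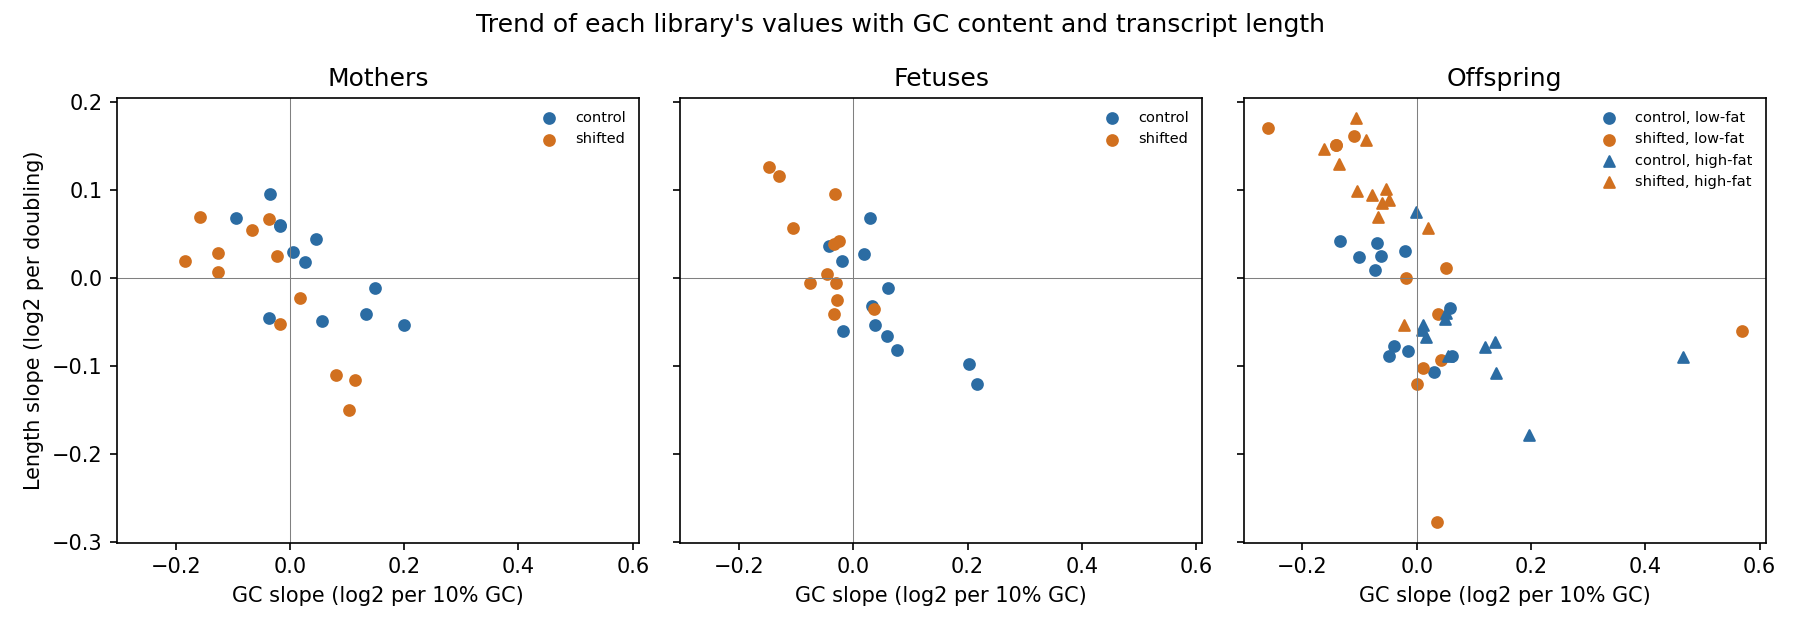
Slope of log2 expression on GC content (per 10% GC) and on transcript length (per doubling) for each library relative to the libraries of its stage, by arm, with a point per library. The mean GC slope was 0.104 in high-fat control and -0.076 in high-fat shifted offspring, and 0.0545 in control and -0.0543 in shifted fetuses.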

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

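The tests on GC content and transcript length in offspring and fetuses, on library batches, on the share of hepatocytes and on the spread of clock genes between replicate mothers were chosen only after the results they bear on were seen.

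The response to the high-fat diet differed between offspring of shifted and of control mothers in 2669 genes by a test of the difference itself, and the lists for fat oxidation and ketogenesis (median log2 difference 0.75), oxidative phosphorylation (-0.29) and endothelial markers (-0.34) passed with the preset correlation. All 3 lists had adjusted p = 0.983 with an estimated correlation, oxidative phosphorylation did not pass after the GC and length correction (0.246) and endothelial markers did not without libraries of low correlation (0.211). Of 100 splits of the libraries, the real one included, 1 gave as many genes (highest other 0). These splits reassigned all offspring arms, so they mixed the diet and maternal level differences into the spread. They therefore cannot decide whether the difference between the diet responses arose by chance. A GC and length bias is a candidate explanation for most of these calls, since 48% of those with a reference transcript were kept after correction. The median size of these calls went from 0.5 (SE 0.14) to 0.34 (SE 0.12) on the log2 scale, so changes became smaller without a wider SE. These genes were picked as called before the correction, which alone favours smaller sizes after it. Daily profiles differed between the arms of mothers in 175 genes and between the arms of low-fat offspring in 12, each by an interaction test. For mothers 1 of 100 splits gave as many (highest other 134), but for low-fat offspring 11 did (highest other 1041), so there chance cannot be excluded. Splits of the arms also mix level differences into these counts. For mothers they argue against arms assigned by chance and do not isolate the interaction. A split with 1041 genes points to some structure of the low-fat libraries other than arm and time, which was not tested. Fetal sex was not in the labels used here, and Xist, which no comparison was built on, was at an FPKM of at least 1 in 4 of 12 control and 6 of 12 shifted fetal libraries.

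Maternal arms differed in 5235 genes in high-fat and in 1 gene in low-fat offspring. Chance assignment of single libraries is argued against for the former (1 of 100 splits, highest other 1347) and not for the latter (10 of 100 splits, highest other 127). These splits treat offspring as independent, and litters are not in the labels, so chance differences between litters stay open. Smooth trends with GC content and transcript length are argued against as the whole cause, since 64.2% of the called genes with a reference transcript were still called in the same direction after those trends were removed. Their median size went from 0.41 (SE 0.1) to 0.29 (SE 0.09) on the log2 scale, so a contribution of those trends stays open, as does a bias of another shape. Sizes also fell for maternal shift by diet (0.5 to 0.34) and in fetuses (0.33 to 0.22), so they do not set these comparisons apart. The share kept also depends on size over SE, so it does not rank this bias between comparisons. Poor low-fat libraries that hide changes are argued against too, since 3 genes were called without them. Batches cannot be told apart from arms, because 0 tables hold libraries of more than 1 arm, and a diet response altered by the maternal schedule stays open as untested beyond these data.

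Fetal arms differed in 440 genes, and 2 of 100 splits gave as many (highest other 715). Chance is argued against only narrowly, without allowance for the number of results tested. The splits treat fetuses as independent, and litters are not in the labels. A split with 715 genes points to some untested structure of the libraries. A GC and length bias is a candidate explanation for most calls, since 31.3% of those with a reference transcript were kept after correction. The median size of the fetal calls went from 0.33 (SE 0.07) to 0.22 (SE 0.06) on the log2 scale, so changes became smaller without a wider SE. Here too the genes were picked as called before the correction, which alone favours smaller sizes. Unequal numbers of male and female fetuses are argued against as the whole cause by 301 genes called with the log2 Xist level as a covariate. A lower share of hepatocytes would raise the markers of every other cell type alike and stays open. Erythroid over macrophage, lymphocyte, stellate and endothelial markers differed between the arms by 0.38, 0.46, 0.3 and 0.17 on the log2 scale. Each lay within 2 SE (0.25, 0.3, 0.21 and 0.2). At the preset correlation the erythroid list rose while the macrophage and lymphocyte lists fell, against that prediction. With an estimated correlation none of these lists passed. A difference in fetal age, on which the hepatocyte maturation list bears without deciding it (median log2 change -0.35, adjusted p = 0.684 with an estimated correlation), stays open, as does an effect of the maternal schedule, which is untested.

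Time of day changed 439 genes in control and 66 in shifted mothers, and clock genes had other profiles. Chance assignment of libraries to times is argued against for control mothers (1 of 100 splits, highest other 244). For shifted mothers 4 of 100 splits gave as many (highest other 734). Without allowance for the number of results tested, that cannot decide on chance there. The count in shifted mothers also fell to 2 without ZT6 replicate 3, and a split with 734 genes points to some untested structure of the libraries. A poor library and a GC and length bias are argued against, since 54 genes were called without ZT18 replicate 3, the shifted library of lowest median correlation (0.953), and 89 after the correction. Shifted mothers of 1 sampling time at different clock phases stay open. The replicate SD of the clock genes was a median of 1.48 times that of control mothers, within the middle 95% of random lists of genes (0.959 to 1.75). Random lists had a median of 1.3 themselves. The test pools all times, so it cannot separate clock phases from a wider spread of genes in general. In shifted replicates 1, 2 and 3, Arntl was at 5.04, 1.17 and 0.561 FPKM at ZT0 and Dbp at 0.802, 4.95 and 25. At ZT12 they were at 0.336, 0.268 and 0.367 and at 19.2, 17.9 and 26.7. A lag of the liver behind the light schedule stays open.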

How the results depend on the processing

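The GC and length correction and the exclusion of libraries with a median correlation under 0.95 were tests chosen only after the data were seen. In the level and maternal shift by diet comparisons no named gene changed direction under the alternatives run. The F tests of time and of its interaction have no direction, and changes of peak time were not checked. The majority of rises over falls turned into falls over rises with the GC and length correction for 3 comparisons of offspring (maternal arms on the high-fat diet 2143 and 2369, diet in shifted offspring 954 and 1060, maternal shift by diet 830 and 885). The reverse held for diet in control offspring (795 and 693). With values as deposited, rises no longer exceeded falls between the fetal arms (90 and 100). The highest level count, 5235 for maternal arms on the high-fat diet, ranged from 4820 to 5907 with each library left out, that for diet in shifted offspring (2591) from 2027 to 3485 and that for maternal shift by diet (2669) from 2212 to 3436.

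Counts that moved by over 1.5 times follow, and the cause was not tested. In control mothers 439 genes changing with time became 246 with the replicate number as a block. In shifted mothers 66 became 14 with no filter and 1 with cosine and sine terms. In low-fat control offspring 1458 became 2257 with cosine and sine terms, and in high-fat control offspring 73 became 377 without libraries of low correlation. The fetal level count of 440 became 190 with values as deposited and 178 with the GC and length correction. The low-fat level count of 1 became 4 with no filter, 2 with only the libraries of the 2 arms and 3 without libraries of low correlation. The diet count in control offspring, 1587, became 884 with only the libraries of the 2 arms. The maternal shift by diet count of 2669 became 1715 with the GC and length correction. The low-fat interaction count of 12 became 37 with no filter, 2 with values as deposited, 29 with upper quartile scaling, 2 with only the libraries of the 2 arms and 227 without libraries of low correlation, and the high-fat count of 0 became 2 without them.

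With each library left out in turn, time of day counts ranged from 204 (without ZT12 replicate 3) to 697 (ZT6 replicate 3) in control mothers, from 2 (ZT6 replicate 3) to 87 (ZT18 replicate 1) in shifted mothers, and were 0 in control fetuses and 0 to 1 (ZT12 replicate 3) in shifted fetuses. They ranged from 450 (ZT6 replicate 3) to 2086 (ZT0 replicate 1) in low-fat control, from 1141 (ZT6 replicate 3) to 3034 (ZT18 replicate 2) in low-fat shifted, from 44 (ZT0 replicate 2) to 158 (ZT0 replicate 1) in high-fat control and from 1506 (ZT0 replicate 1) to 4715 (ZT18 replicate 3) in high-fat shifted offspring. Level counts ranged from 514 (control ZT18 replicate 1) to 1199 (shifted ZT18 replicate 1) in mothers, from 213 (control ZT6 replicate 2) to 870 (shifted ZT0 replicate 3) in fetuses, from 1 to 28 (shifted ZT0 replicate 2) in low-fat offspring and from 1056 (low-fat ZT6 replicate 2) to 2599 (high-fat ZT12 replicate 1) for diet in control offspring. Interaction counts ranged from 101 (control ZT18 replicate 2) to 243 (shifted ZT18 replicate 1) in mothers, from 0 (control ZT18 replicate 3) to 419 (control ZT18 replicate 1) in low-fat and from 0 to 3 (control ZT12 replicate 1) in high-fat offspring, and were 0 in fetuses.

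Values as deposited moved the median log2 change of all genes to 0.208 for maternal arms on the high-fat diet, -0.131 for diet in control offspring and 0.173 for maternal shift by diet, so rises against falls went from 3083 and 2152 to 4972 and 907, from 717 and 870 to 345 and 2014, and from 1646 and 1023 to 2774 and 391. In mothers they went from 359 and 512 to 121 and 1134. Depth is unknown, so how far it limits low values was not computed.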

Other observations

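The GC and length correction and the summary of peak times were chosen after the data were seen, whereas the test on rhythmic genes outside the clock list was chosen before its value was seen.

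Mothers and fetuses shared 74 genes called between shifted and control arms, against 32.7 expected if independent, and 74 moved the same way, against 16 expected (Spearman 0.22 across genes, which are not independent replicates). Against the change in low-fat offspring the correlation was -0.39 for mothers and -0.19 for fetuses (-0.31 and -0.18 after the GC and length correction). After the GC and length correction mothers and fetuses shared 46 genes, against 12.3 expected, and 46 moved the same way, against 6 expected. Independence is not given, since the mean GC slope was lower in the shifted arm of both stages (mothers 0.0347 in control and -0.0348 in shifted, fetuses 0.0545 and -0.0543). Library batches that follow the arms in both stages, or related mothers and fetuses, could raise the overlap, which was not tested. Fetal livers varied widely in genes switched on late in development. G6pc ran from 0.11 to 82.1 FPKM in control (median 14.8) and from 0.215 to 68.9 in shifted fetuses (median 1.9), and Cyp2e1 from 1.84 to 306 (median 28.2) and from 1.16 to 119 (median 10.2, n = 12 each). Neither passed between the arms (adjusted p = 0.398 and 0.43). Afp ran from 11400 to 18200 and from 11500 to 18800.

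Lists that passed in no level comparison had smallest adjusted p of 0.0533 (bile acid synthesis and transport), 0.075 (glucocorticoid-responsive), 0.112 (xenobiotic metabolism, growth hormone and IGF axis, neutrophils), 0.124 (male-biased), 0.131 (lipid-associated macrophages), 0.133 (core clock), 0.146 (cholesterol synthesis), 0.2 (cholangiocytes), 0.222 (acute phase, female-biased), 0.24 (hepatoblasts), 0.508 (pancreatic acinar cells) and 0.661 (megakaryocytes). Adipocyte, skeletal muscle and placenta lists had fewer than 3 measured members.

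A hypothesis was that livers of shifted mothers lagged behind the advanced light schedule, which would move peaks of rhythmic genes outside the clock list later too, by up to 8 h. The 424 other genes called in control mothers peaked later by a circular mean of 6.2 h in shifted mothers, 349 of them (82.3%) later. Single differences ran from -11.8 to 11.9 h. Of 408 genes called in control mothers and measured in both arms, clock genes included, 31 were called in shifted mothers. Most of these peaks were thus fitted without a called rhythm there, and in the same libraries as the clock genes. Such a lag predicts this direction and stays open. It may depend on the day of sampling after an advance, and that day is not in the labels. Meal times were not given.

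Splits of the libraries for the other results, 100 each with the real one included, were as follows. Chance assignment of single libraries is argued against for time of day in low-fat control offspring (1 split with as many genes, real 1458, highest other 17). The same holds for low-fat shifted (1, 2530, 493), high-fat control (1, 73, 1) and high-fat shifted offspring (1, 3018, 137). It also holds for the level comparison of mothers (1, 871, 191) and for diet in control (1, 1587, 491) and shifted offspring (1, 2591, 1579), with the highest other count in the last. These splits treat libraries as independent, without litters, and make no allowance for the number of results tested. Where limma called 0 genes, 100 of 100 splits give as many whatever the data, which says nothing about chance: time of day in control (529 at an unadjusted p under 0.05, highest other 2407) and shifted fetuses (615, 2045), and the interactions of fetuses (419, 3675) and high-fat offspring (872, 2288). Other splits with counts that high point to some structure of the libraries, which was not tested.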
